A study of Homo sapiens with 18 samples.

How the data were processed

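Gene expression was measured on 18 arrays of 3 hepatocellular carcinoma cell lines, with 3 arrays of each line after transfection with an siRNA against ATAD2 and 3 after transfection with a control siRNA. The groups were taken from the sample labels, which call the samples biological replicates. The labels name the treated samples knockouts, whereas the series design and the treatment protocol describe siRNA, and the treated samples are described here as knockdowns. Total RNA was extracted with a commercial kit and labelled with biotin, per the labels' protocols.

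The deposited values form 1 table of 54675 probe sets by 18 arrays, on a log2 scale as judged from their range of 1.33 to 14.0. The background correction and normalization are not given in the sources used here, and limma is the only tool named in the submitters' processing notes, without a version. Sorted columns differed by at most 0.16 log2 units within a line and by up to 1.51 between lines, so that the lines had the look of values normalized separately. By a rule set before the data were examined, the columns were therefore quantile normalized over all 18 arrays, and the values as deposited were kept as an alternative. All levels and log2 changes reported are on this log2 scale. A fold change understates the change of a gene whose signal lies near the background of the array.

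Probe sets were named from the platform annotation. It listed 1 gene for 41097 probe sets, several genes for 1801 and no gene for 11777. Symbols of 41043 of the probe sets with 1 gene were updated by gene identifier from a RefSeq table of the assembly GRCh38.p14, which was used for names only. No genome sequence was used, and no coordinates are given. Each gene was represented by its probe set with the highest mean over all arrays, which left 19777 genes, of which 10523 had more than 1 probe set. Probe sets with several genes or no gene did not enter the gene tests.

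A linear model with 1 mean for each of the 6 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual and 4.01 prior degrees of freedom). All groups shared 1 estimate of the spread. The contrasts were ATAD2 siRNA minus control in each line, the mean of these 3 differences, the differences between lines (an F test over the interaction contrasts, and each pair of lines), and the control arrays of each pair of lines. P-values were two-sided and adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05. The comparison of control arrays also asked for an absolute log2 difference of at least 1. With 3 arrays against 3, an exact permutation test of a single gene cannot give a two-sided p under 0.1, so that no such test is reported. The p-values rest on the spread between biological replicates as labelled, pooled for each gene over the 6 groups, and the number of arrays limits their precision. A group with a wider spread than the others, such as the ATAD2 siRNA arrays of PLC, is thus judged by a spread narrower than its own.

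Gene lists, 27 in all, were fixed before the data were examined. Each was tested with camera at a preset correlation of 0.01, with adjustment over the lists within a contrast. Camera with a correlation estimated from the data and fry were run as alternatives. For each list the members past the threshold were counted with p-values adjusted over all genes and with p-values adjusted over the list alone. The genes named in the text were chosen by a rule fixed beforehand. They are ATAD2, the 10 genes with the largest rise and the 10 with the largest fall in each line among genes past the threshold whose knockdown values all lay on one side of all control values, and up to 10 genes per direction past the threshold in all 3 lines. Further named genes are 5 genes with opposite changes and 5 others with the smallest interaction p, up to 4 members of each list with the largest change past the threshold, and, for the control arrays, members of the lineage lists. Genes on the Y chromosome and XIST were left out. RB1 was chosen after its values were seen.

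The procedure was tested on simulated data for the same 19777 genes, with log2 changes of 0.5 and of 1 given to 100 genes each in a line. It recovered 73% of the smaller and 98% of the larger changes in Hep3B, 75% and 97% in SNU449, and 79% and 97% in PLC, and called 14, 5 and 8 unchanged genes. The simulated noise was independent between arrays, with 1 spread per gene over all groups and no array of lower quality. These shares need not hold where groups differ in spread, as the ATAD2 siRNA arrays of PLC did.

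The alternatives tried were the values as deposited, quantile normalization within each line, centring each array on its median, leaving out the dimmest 30% or 50% of genes, the mean of all probe sets of a gene, every probe set by itself, each line fitted by itself, an intensity trend with a robust prior, a replicate block, a stricter threshold of 0.01, an absolute log2 change of at least 1 (no such minimum for the control arrays), and leaving out each array in turn. Signal of the array's own control probe sets was examined after the data were seen. It gave 3 added alternatives, which left out PLC siATAD2 replicates 1 and 3 together, added the difference between 5' and 3' signal of beta-actin and GAPDH as a covariate, or weighted the arrays by quality. Replicate numbers were not taken to pair samples across groups, since the labels name no shared culture or day.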

Results

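ATAD2, a chromatin-bound ATPase with a bromodomain, was knocked down with siRNA in Hep3B, SNU449 and PLC (PLC/PRF/5), 3 established cell lines from human hepatocellular carcinoma. The series was set up to evaluate ATAD2 as a target in this cancer. Each line gave 3 arrays with ATAD2 siRNA and 3 with a control siRNA, 18 in all. The median of the deposited log2 values was 5.39, 5.42 and 5.41 on the Hep3B control arrays and 5.37, 5.36 and 5.38 on the Hep3B ATAD2 siRNA arrays. It was 5.61, 5.61 and 5.62 on the SNU449 control arrays and 5.58, 5.59 and 5.55 after ATAD2 siRNA, and 4.17, 4.16 and 4.14 on the PLC control arrays and 4.21, 4.16 and 4.17 after ATAD2 siRNA. The normalization and any centring behind these values stay unknown, and the log2 scale was judged from their range. No array held the same values as another, and arrays of a group correlated with Pearson's r of 0.994 to 0.998 across probe sets. The median standard deviation of a gene within a group was 0.0701 to 0.0726 log2 units on control arrays, and 0.0931, 0.0661 and 0.118 on the ATAD2 siRNA arrays of Hep3B, SNU449 and PLC.

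ATAD2 mRNA was lower on every knockdown array than on every control array of the same line. In Hep3B the log2 signal of its main probe set was 8.94, 8.93 and 9.02 on the control arrays and 5.15, 4.70 and 5.65 on the ATAD2 siRNA arrays, a log2 change of -3.80 ± 0.16 (SE), or 13.9-fold (limma, adjusted p = 1.42e-10). In SNU449 it was 9.32, 9.18 and 9.14 against 6.62, 6.90 and 6.96, a change of -2.39 ± 0.16 or 5.23-fold (adjusted p = 6.16e-07). In PLC it was 9.78, 9.67 and 9.69 against 7.05, 7.17 and 7.06, a change of -2.62 ± 0.16 or 6.14-fold (adjusted p = 3.04e-07). All 4 ATAD2 probe sets were lower in each line, with the smallest change, -1.03, for 1 probe set in PLC. The size of the reduction of the main probe set differed between the lines (interaction adjusted p = 0.00137), but the order of the lines depended on the probe set. Another probe set of ATAD2 fell 5.04-fold in Hep3B, 5.59-fold in SNU449 and 2.04-fold in PLC.

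**Figure D1:**
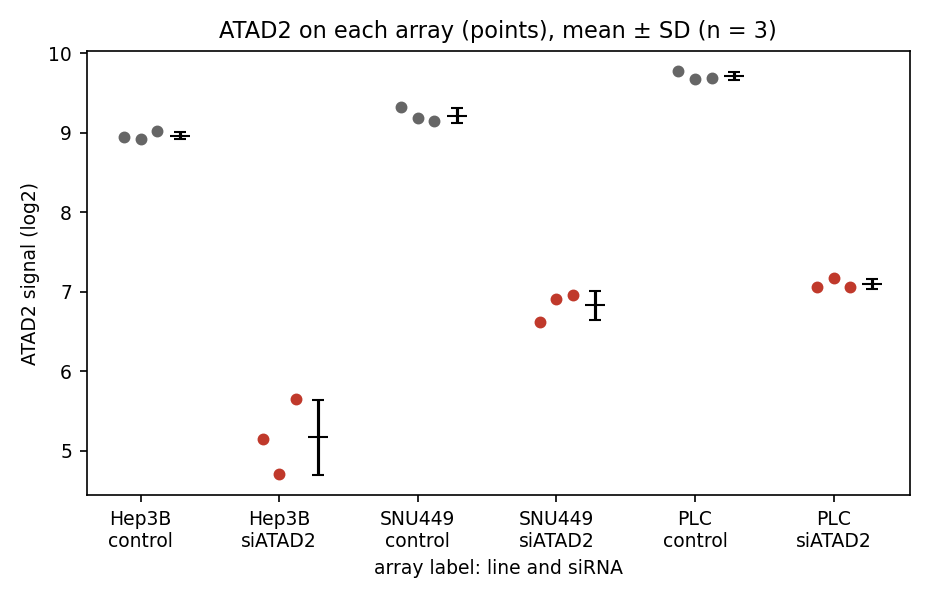
Log2 signal of the main ATAD2 probe set on each of the 18 arrays, by line label and siRNA, with 1 point per array and bars of the mean ± SD (n = 3). Control arrays lie between 8.93 and 9.78 and ATAD2 siRNA arrays between 4.70 and 7.17.

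The control arrays showed how the cell lines differed before knockdown. Arrays labelled SNU449 carried a strong hepatocyte profile, and arrays labelled Hep3B a mesenchymal one. Albumin (ALB) had a log2 signal of 13.8 ± 0.02 (SD, n = 3) under the SNU449 label, 10.6 ± 0.07 in PLC and 3.03 ± 0.13 under the Hep3B label, and alpha-fetoprotein (AFP), the fetal plasma protein used as a marker of liver cancer, 9.29, 7.53 and 5.15. The oncofetal proteoglycan gene GPC3 had a signal of 12.1, 7.07 and 4.78, and the epithelial adhesion gene EPCAM one of 12.5, 6.09 and 2.73. Of 49 hepatocyte genes, 34 were higher and 3 lower by at least 1 log2 unit under the SNU449 label than under the Hep3B label, and FGB, the fibrinogen beta chain, was among the lower ones (6.88 against 11.5). In the other direction, the receptor tyrosine kinase gene AXL had a signal of 10.8 on the Hep3B-labelled arrays and 3.46 on the SNU449-labelled ones, COL1A2 12.4 and 5.54, SPARC 9.87 and 3.51, the transcription factor gene ZEB1 8.998 and 4.08, and vimentin (VIM) 13.3 and 11.6. Of 43 mesenchymal and matrix genes, 20 were lower and 2 higher under the SNU449 label. The epithelial list was mixed, since 13 of 28 members, CDH1 and KRT19 among them, were higher under the SNU449 label and 3 lower, KRT7 with 5.16 against 11.1.

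These levels run against the usual description of the cell lines, in which Hep3B makes plasma proteins and AFP and SNU449 is poorly differentiated. RB1, which Hep3B is known to lack, was chosen after its values were seen. Its signal was 4.44 ± 0.18 (SD, n = 3) on the control arrays labelled SNU449, 9.47 ± 0.03 on those labelled Hep3B and 8.57 ± 0.02 on those of PLC, a log2 difference of -5.03 between the first pair (limma, adjusted p = 7.05e-18). The ATAD2 siRNA arrays of each label followed their controls, with RB1 between 4.27 and 4.75 on all 6 arrays labelled SNU449 and between 9.15 and 9.51 on all 6 labelled Hep3B. The groups keep their labels, and Hep3B and SNU449 stand for the arrays so labelled. Comparisons of knockdown with control lie within a label.

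**Figure D2:**
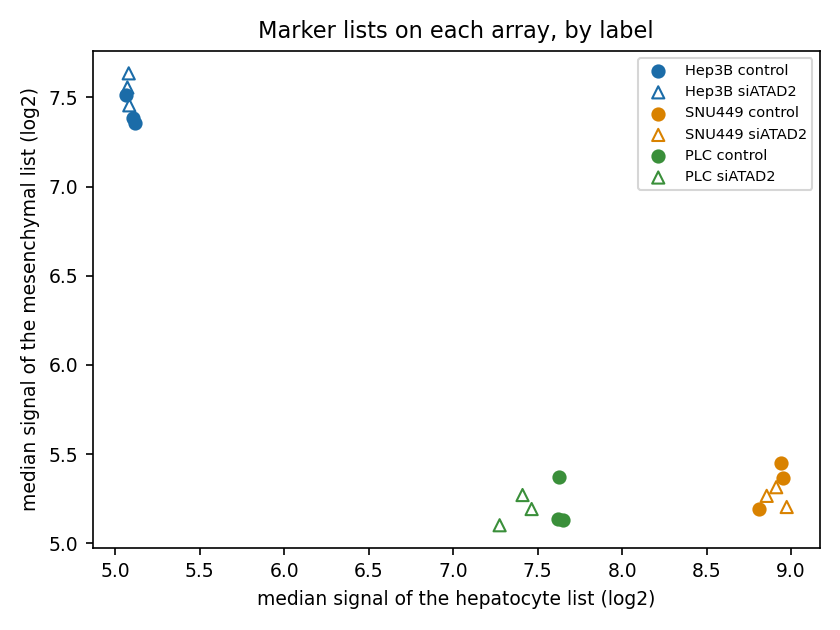
Median signal of the mesenchymal list against that of the hepatocyte list (log2), by line label, with 1 point per array (filled for control, open for ATAD2 siRNA). The hepatocyte median lies between 8.81 and 8.97 on the arrays labelled SNU449, 7.28 and 7.65 on those of PLC and 5.06 and 5.12 on those labelled Hep3B, where the mesenchymal median is 7.36 to 7.64.

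PLC lay between the other labels in hepatocyte genes but not in mesenchymal ones. Of the hepatocyte genes, 30 were higher and 1 lower in PLC than in Hep3B, and 27 were higher and 5 lower in SNU449 than in PLC, where CPS1, a urea cycle enzyme gene, was higher in PLC (11.7 against 8.85). Of the 43 mesenchymal and matrix genes, 1 was higher and 20 were lower in PLC than in Hep3B, and the list's median on the PLC arrays (5.10 to 5.37) was near that on the SNU449-labelled ones (5.19 to 5.45). COL1A2 had a signal of 4.90 in PLC, whereas ZEB1 at 8.60 and AXL at 8.51 were nearer to Hep3B. Among leukocyte and endothelial markers, the lysozyme gene LYZ had a signal of 12.1 in SNU449 and 11.1 in PLC against 2.37 in Hep3B, while the leukocyte gene PTPRC lay between 2.77 and 3.66. With limma, 3899 genes differed by at least 1 log2 unit between SNU449 and Hep3B, 3642 between PLC and Hep3B and 3793 between SNU449 and PLC. On the deposited values the counts with PLC were 8511 and 9424.

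In arrays labelled Hep3B the knockdown changed the largest number of genes. ADAMTS3, a procollagen protease gene, rose by 2.05 ± 0.10 (log2 ± SE, n = 3 each), or 4.15-fold, TECPR2 by 1.71, the adrenergic receptor gene ADRB1 by 1.63, the desmosomal cadherin gene DSC2 by 1.57 and RGCC by 1.55. The chemokine gene CXCL6 and the carboxypeptidase gene CPA4 each rose by 1.42, the urea transporter gene SLC14A1 by 1.40, the pluripotency factor gene SOX2 by 1.33 and ZNF367 by 1.32. After ATAD2, the mitochondrial ribosome gene MRPS33 fell by 2.22 ± 0.08, or 4.66-fold, TXNDC16 fell by 2.20, the zinc transporter gene SLC39A10 by 2.04, LINC00621 by 2.04, TMF1 by 2.01, FOS by 1.83, ASZ1 by 1.77, the nuclear import gene HIKESHI by 1.71 and the tyrosine kinase gene FRK by 1.68. In the limma fit 1717 genes were higher and 1530 lower, 16.4% of 19777, and 97 of these changed by at least 1 log2 unit. FOS was uneven, with -0.64, -3.87 and -0.99 on the ATAD2 siRNA arrays against the control mean, and its call (adjusted p = 0.0291) was lost without Hep3B control replicate 1 (adjusted p = 0.0821) or 3 (0.116), with the line fitted by itself (0.141) and with an intensity trend (0.0597). Of the 20 genes with the largest changes, 10 had a single probe set, for 5 (TECPR2, ADRB1, RGCC, SOX2 and FRK) no other probe set passed the threshold. For TMF1 1 of 5 other probe sets was called in the opposite direction, so that the mean of its probe sets changed by -0.11 (adjusted p = 0.482).

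Genes of DNA replication fell together in Hep3B. Of 53 E2F and G1/S genes, 34 fell and 0 rose in the limma fit (44 fell when adjusted over the list alone), with a median log2 change of -0.26 (camera adjusted p = 2.49e-17; adjusted p = 0.0642 with an estimated correlation). UHRF1, which couples DNA methylation to replication, fell by 0.79, the uracil glycosylase gene UNG by 0.58, E2F2 by 0.48 and cyclin E1 (CCNE1) by 0.45. Of 14 genes earlier linked to ATAD2 in cell cycle and growth, 6 fell (7 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 7.23e-05; adjusted p = 0.0642 with an estimated correlation). Among them cyclin D1 (CCND1) fell by 0.92 and the kinase gene SGK1 by 0.74. The median of this list was -0.13, -0.37 and -0.13 on the ATAD2 siRNA arrays, and without replicate 2 it was -0.11 (camera adjusted p = 0.000988). Of 56 G2/M genes, 14 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 7.23e-05; adjusted p = 0.470 with an estimated correlation). DLGAP5 fell by 0.63, HMMR by 0.52, KIF18A by 0.47 and NUF2 by 0.44. Without Hep3B ATAD2 siRNA replicate 2 the G2/M median was -0.07 and the list did not pass (camera adjusted p = 0.0807).

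Several metabolic and signalling lists also passed camera in Hep3B, and for none of these did the call hold with an estimated correlation. Of 19 sterol biosynthesis genes, 7 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00111; adjusted p = 0.173 with an estimated correlation), with the synthase gene HMGCS1 up by 0.71, SC5D by 0.61 and INSIG1 by 0.52. Of 29 fatty acid genes, 11 rose and 1 fell, the same counts adjusted over the list alone (camera adjusted p = 0.00188; adjusted p = 0.0517 with an estimated correlation), with PPARA up by 0.55 and the elongase gene ELOVL6 by 0.48. Without Hep3B ATAD2 siRNA replicate 1 the sterol median was 0.16 in place of 0.25 and the fatty acid median 0.11 in place of 0.07. Of 33 hypoxia and glycolysis genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.00108; adjusted p = 0.281 with an estimated correlation). VEGFA, the angiogenic factor gene, fell by 0.99, adrenomedullin (ADM) by 0.70 and the glucose transporter gene SLC2A1 by 0.53. The median of the hypoxia list was -0.18, -0.01 and -0.18 on the ATAD2 siRNA arrays, so that replicate 2 showed little of the fall. It was -0.17 without replicate 2 and -0.07 without replicate 3 in place of -0.11. Of 32 oxidative phosphorylation genes, 6 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.00375; adjusted p = 0.281 with an estimated correlation), with SDHC down at -0.34, and the call was lost when arrays were centred on their medians (0.0954). Of 27 autophagy and lysosome genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.00188; adjusted p = 0.281 with an estimated correlation), with the lysosomal regulator gene TFEB up by 0.55. The median of the autophagy list was 0.10, 0.25 and 0.07 on the ATAD2 siRNA arrays, and without replicate 2 it was 0.09 in place of 0.16 (camera adjusted p = 0.0164). Without the dimmest 50% of genes the fatty acid and autophagy calls were lost (0.0515 each).

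In 4 further lists of Hep3B the call also depended on single arrays and on the processing. Immediate early genes were lower, 8 of 25 with 2 higher (9 and 3 adjusted over the list alone; camera adjusted p = 0.0415; adjusted p = 0.491 with an estimated correlation). They included FOS, EGR1 at -1.48, ATF3 at -1.32 and DUSP1 at -1.19. Integrated stress and unfolded protein response genes had 16 members up and 6 down of 36 (19 and 8 adjusted over the list alone), with a median of 0.16 and a mean of 0.03 (camera adjusted p = 0.0161; adjusted p = 0.173 with an estimated correlation). The largest changes in that list were falls, of ATF3, of the folate enzyme gene MTHFD2 (-0.66) and of the amino acid transporter gene SLC7A5 (-0.61). Of 21 NRF2 targets, 4 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00400; adjusted p = 0.470 with an estimated correlation), with the heme oxygenase gene HMOX1 at 0.50 and the malic enzyme gene ME1 at -0.37. Of 29 NF-kB and inflammatory genes, 5 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.0482; adjusted p = 0.198 with an estimated correlation), with CXCL1 at 0.63 and ICAM1 at 0.58. Without Hep3B ATAD2 siRNA replicate 2 the adjusted p was 0.281 for the NRF2 list and 0.0534 for each of the other lists. Without Hep3B control replicate 3 it was 0.0678 and without SNU449 control replicate 1 0.0552 for the immediate early list. For the inflammatory list it was 0.0838 without Hep3B control replicate 1, 0.0532 without SNU449 control replicate 1 and 0.0601 without PLC ATAD2 siRNA replicate 2. Over 30 settings the inflammatory call was lost in 11 (adjusted p up to 0.313), 0.0660 with the 5' and 3' covariate among them. The immediate early call was lost in 8 (up to 0.491), the NRF2 call in 5 (up to 0.470) and the stress response call in 4 (up to 0.173). On Hep3B ATAD2 siRNA replicate 2 the difference between 5' and 3' signal of beta-actin and GAPDH was -0.39, against -0.69 and -0.65 on the other ATAD2 siRNA arrays of the line and -0.58 to -0.71 on its controls.

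**Figure D3:**
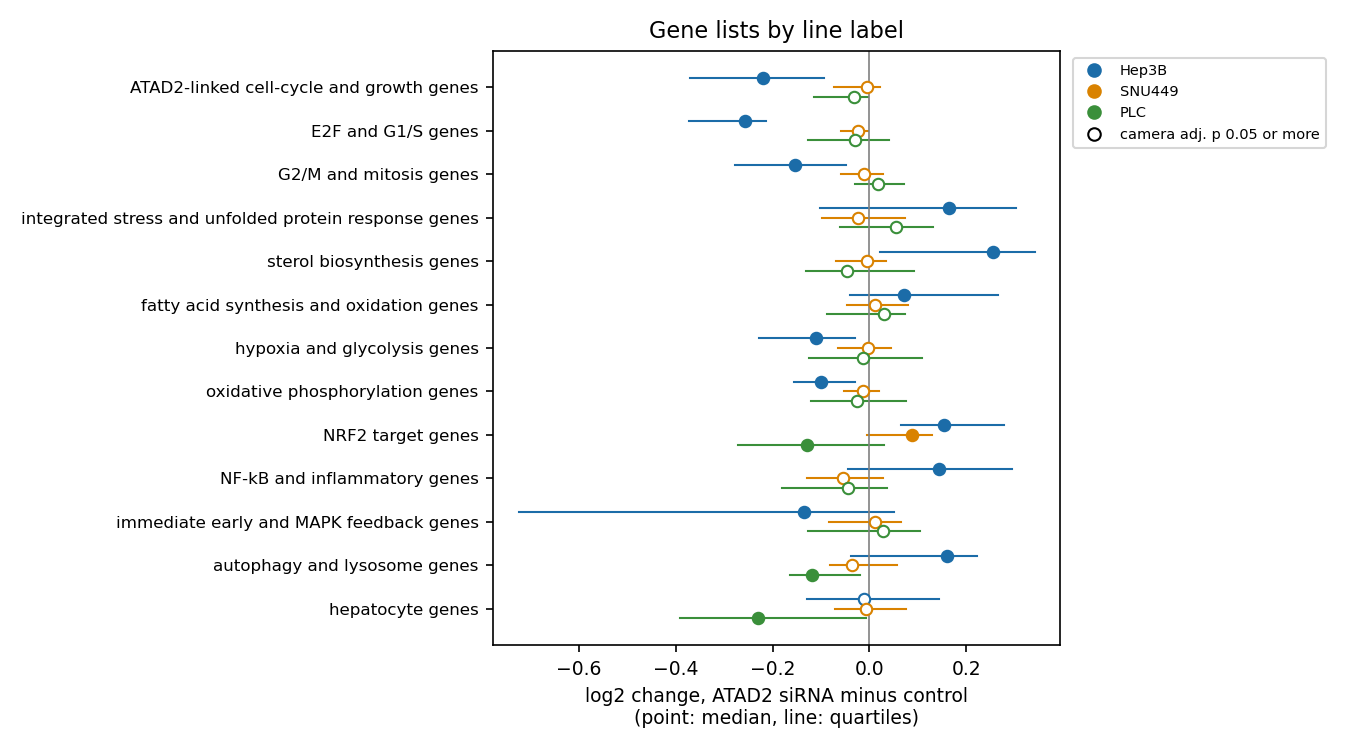
Median log2 change (ATAD2 siRNA minus control) of the members of each gene list that passed camera in at least 1 line, by line label, with lines spanning the quartiles and filled points for an adjusted p under 0.05. The E2F and G1/S list has a median of -0.26 in Hep3B, -0.02 in SNU449 and -0.03 in PLC, and the hepatocyte list one of -0.23 in PLC.

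In arrays labelled SNU449 few genes changed. CFDP1, a chromatin-associated gene, rose by 0.73 ± 0.05 (log2 ± SE, n = 3 each), or 1.66-fold (limma, adjusted p = 4.94e-07), the peroxisomal acyltransferase gene CROT by 0.68, the proprotein convertase gene PCSK5 by 0.66, and FABP1, the liver fatty acid binding protein gene, by 0.64. CHST9 rose by 0.54, the transcription factor gene KLF4 by 0.51, CPEB2 by 0.50, the growth factor gene EREG by 0.49, TM4SF1 by 0.47 and PAPSS2 by 0.47. After ATAD2, the calprotectin gene S100A8 fell by 0.92, the tubulin gene TUBA1A by 0.82, MRPS33 by 0.78, the glycoprotein hormone alpha chain gene CGA by 0.54, RNASE1 by 0.51, the endothelin gene EDN1 by 0.50, PTGDS by 0.49, the calcium pump gene ATP2B4 by 0.46 and CPS1 by 0.46. In the limma fit 29 genes were higher and 22 lower, and 2042 had an unadjusted p under 0.05. Besides ATAD2, the lists held 3 called members, KLF4 and the hepatocyte genes FABP1 and CPS1. The NRF2 list was the only one of 27 to pass camera, with a median of 0.09, 0 of 21 members past the threshold in limma and 1 higher when adjusted over the list alone (camera adjusted p = 0.0215; adjusted p = 0.761 with an estimated correlation), and it did not pass without SNU449 control replicate 2 (0.113) or ATAD2 siRNA replicate 2 (0.130). Over 30 settings the call was lost in 7.

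The SNU449 count moved with single arrays. In place of 51 genes, limma called 11 without SNU449 control replicate 2, 22 without control replicate 3, 10 without ATAD2 siRNA replicate 2 and 13 without ATAD2 siRNA replicate 3, and 82 and 86 without ATAD2 siRNA replicate 2 of Hep3B and of PLC, arrays that share the estimate of the spread. Of the 20 genes named for this line, 7, ATAD2 among them, kept their call without each array in turn. For 15, CFDP1 among them, no other probe set of the gene passed the threshold.

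In PLC, genes of hepatocyte function were lower after knockdown. ALB fell by 1.02 ± 0.14 (log2 ± SE, n = 3 each), or 2.03-fold (limma, adjusted p = 0.000985), the apolipoprotein gene APOC3 by 0.92 (adjusted p = 4.09e-05) and ORM1, which encodes an acute phase plasma protein, by 0.82 (adjusted p = 3.45e-06). Of 49 hepatocyte genes, 19 fell and 1 rose, the coagulation factor gene F9 (21 and 2 adjusted over the list alone), with a median of -0.23 and 37 members below 0 (camera adjusted p = 1.07e-11; adjusted p = 0.00773 with an estimated correlation). The list's median was -0.22, -0.18 and -0.26 on the ATAD2 siRNA arrays against the control mean. ALB, APOC3 and ORM1 kept an adjusted p under 0.05 in each alternative fit of genes, although APOC3 and ORM1 changed by less than 1 log2 unit, while F9, with a control signal of 2.99, lost it with the line fitted by itself (adjusted p = 0.272).

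Of the 20 genes with the largest changes in PLC, 12 had a single probe set, and for 6, APOC3, ADRB1 and DSC2 among them, no other probe set passed the threshold. Most of the other large changes were in dim genes. ADRB1 rose by 0.93 and DSC2 by 0.75, from control signals of 6.81 and 7.43. F9 rose by 0.98, CCDC89 by 0.98, the small proteoglycan genes OGN and OMD by 0.97 and 0.84, CPNE4 by 0.90, ALG14-AS1 by 0.79, DLEU7 by 0.75 and the sperm phospholipase gene PLCZ1 by 0.74, all from control signals of 2.36 to 3.19. TXNDC16 fell by 1.22 from 7.61, and BABAM2-AS1 fell by 0.96, PLA2G2F by 0.87, BLID by 0.86, TMEM200A by 0.83 and METTL21C by 0.81, from control signals of 3.02 to 4.14. In other lists, AKR1C3, AKR1C2 and AKR1C1, genes of aldo-keto reductases, fell by 0.52, 0.45 and 0.39, the cadherin gene CDH1 by 0.57, thrombospondin 1 (THBS1) by 0.47, MYC by 0.37, RFC2 by 0.36 and MCM2 by 0.32, while the death receptor genes TNFRSF10A and TNFRSF10B rose by 0.37 and 0.35. The E2F and G1/S list, with 3 of 53 members lower (6 adjusted over the list alone) and a median of -0.03, did not pass camera (adjusted p = 0.127). It passed with the 5' minus 3' signal of beta-actin and GAPDH as a covariate, at a median of -0.07 (0.0129).

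The PLC knockdown arrays were uneven in quality. The mean difference between 5' and 3' signal of beta-actin and GAPDH was -1.16 and -1.08 on ATAD2 siRNA replicates 1 and 3, against -0.47 on replicate 2 and -0.44 to -0.57 on the controls. Poly-A spike-ins, which are added to the RNA, differed alike on these arrays (-2.49 and -2.40 against -1.52). The NRF2 list (median -0.13, 3 of 21 members lower, 7 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00298; adjusted p = 0.641 with an estimated correlation) and the autophagy and lysosome list (median -0.12, 1 lower and 1 higher of 27, also adjusted over the list alone, camera adjusted p = 0.0310; adjusted p = 0.641 with an estimated correlation) moved with these arrays. Their medians were -0.14 and -0.17 on replicate 1, -0.21 and -0.07 on replicate 3, and -0.03 and 0.01 on replicate 2. With the difference in 5' and 3' signal as a covariate neither passed, at medians of 0.000446 and -0.02 (adjusted p = 0.545 and 0.908), nor did either pass without replicates 1 and 3 (-0.03 and 0.01, adjusted p = 0.186 and 0.994). The covariate also brought the oxidative phosphorylation list past the threshold in PLC (median -0.05 in place of -0.03, adjusted p = 0.0440). The autophagy list also failed without PLC control replicate 2 (0.0890) or 3 (0.0544) or without ATAD2 siRNA replicate 1 (0.324) or 3 (0.0622). The hepatocyte list passed in both cases, but with the covariate its median shrank from -0.23 to -0.14.

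In the limma fit of PLC 462 genes were higher and 442 lower. With PLC fitted by itself 3 were higher and 12 lower, and of the 20 genes with the largest changes 6 kept their call, namely ATAD2, TXNDC16, ALB, APOC3, ORM1 and DSC2. The total of 904 became 3215 without ATAD2 siRNA replicate 2, 477 without replicate 1, 593 without replicate 3, 442, 402 and 449 without control replicates 1, 2 and 3, and 394 with the 5' and 3' covariate. Without ATAD2 siRNA replicates 1 and 3 it was 874, where the remaining array is taken to vary like the other groups.

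**Figure D4:**
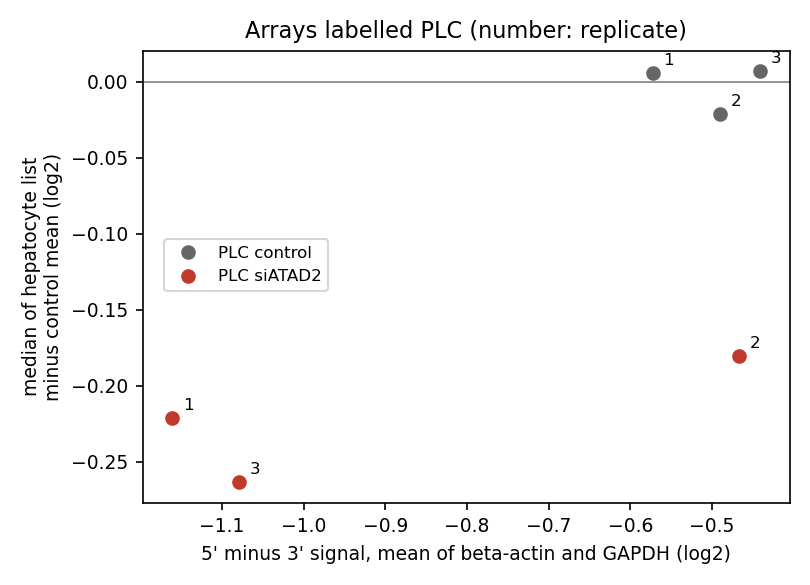
Hepatocyte list median against the control mean (log2) and the mean 5' minus 3' signal of beta-actin and GAPDH (log2) on the 6 PLC arrays. The ATAD2 siRNA arrays lie at -0.22, -0.18 and -0.26 for the list, whereas 5' minus 3' signal is low on replicates 1 and 3 alone (-1.16 and -1.08).

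Scaling set the balance of rises and falls. The share of called genes that were higher was 52.9% in Hep3B, 56.9% in SNU449 and 51.1% in PLC. On the deposited values it was 64.2%, 70.6% and 34.5%, and with each array centred on its median 75.1%, 85.1% and 22.6%. The median change of all genes lay within 0.1 log2 units of 0 in each of these cases.

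A small set of genes changed in the same direction in all 3 lines. DESI2 rose by 1.16 in Hep3B, 0.29 in SNU449 and 0.63 in PLC, C19orf12 by 0.96, 0.37 and 0.53, SMIM15 by 1.06, 0.36 and 0.28, DENND5B by 0.76, 0.34 and 0.43, and the translesion polymerase gene REV3L by 0.74, 0.34 and 0.30 (SE 0.06 to 0.07). The laminin gene LAMC1 rose by 0.41, 0.34 and 0.39 and ITPRIPL2 by 0.39, 0.40 and 0.30. Besides ATAD2, the changes of genes that fell in each line were -2.20, -0.45 and -1.22 for TXNDC16, -2.22, -0.78 and -0.75 for MRPS33, -1.71, -0.40 and -0.38 for HIKESHI, and -0.80, -0.43 and -0.54 for the transcription factor gene ZIC2. They were -0.64, -0.36 and -0.67 for IGFBP3, which encodes an insulin-like growth factor binding protein, and -0.83, -0.50 and -0.33 for EDN1. The 7 higher and 7 lower genes, with the siRNA target ATAD2 among the lower, compare with 0.0588 and 0.0380 expected from independent lists of these sizes. The lines share 1 estimate of the spread per gene, so their lists are not independent and these expected counts may be too low. ATAD2 and MRPS33 stayed in the set in each alternative fit of genes at an adjusted p under 0.05, but with an absolute log2 change of at least 1 in each line the set held 1 gene, ATAD2. The set held these 2 genes alone with a replicate block, ATAD2 and MRPS33, and 3 genes with each line fitted by itself, where TXNDC16 was the other. With the mean of all probe sets of a gene the set held 8 genes. ATAD2, HIKESHI, IGFBP3, MRPS33, TXNDC16 and ZIC2 stayed in it, whereas EDN1 and all the rises named above left it. Leaving out single arrays gave sets of 3 genes (without SNU449 control or ATAD2 siRNA replicate 2) to 25 (without PLC ATAD2 siRNA replicate 2), with 4 and 5 genes without SNU449 ATAD2 siRNA and control replicate 3, 7 without Hep3B control replicate 2, SNU449 ATAD2 siRNA replicate 1 or PLC control replicate 1 or 2, 8 without Hep3B control replicate 3, and 9 without Hep3B control replicate 1, Hep3B ATAD2 siRNA replicate 3 or PLC control replicate 3.

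**Figure D5:**
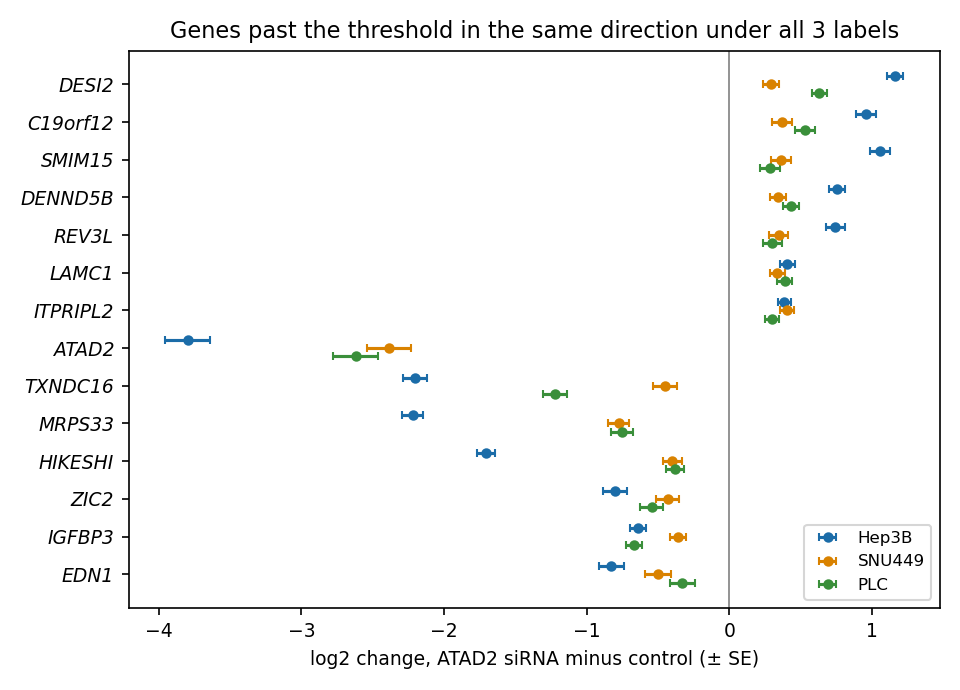
Log2 change (ATAD2 siRNA minus control, bars of 1 SE) of the 14 genes changed in the same direction in all 3 lines, by line label. ATAD2 changed by -3.80, -2.39 and -2.62, and LAMC1 rose by 0.41, 0.34 and 0.39.

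Pairs of lines shared more genes than independent lists would, although all lines share 1 estimate of the spread per gene. Hep3B and PLC shared 128 higher and 112 lower genes, against 40.1 and 34.2 expected, Hep3B and SNU449 shared 18 and 11 against 2.52 and 1.70, and SNU449 and PLC shared 7 and 7 against 0.677 and 0.492. Across all 19777 genes, which are not independent replicates, the log2 changes correlated with Pearson's r of 0.296 between Hep3B and SNU449, 0.137 between Hep3B and PLC and 0.0439 between SNU449 and PLC.

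For the mean change over the lines, limma called 1344 genes higher and 1234 lower, 62.2% of calls higher on the deposited values and 74.1% after median centring in place of 52.1%. Each list that passed camera for the mean passed in a single line of the main fit, hepatocyte genes in PLC and the others in Hep3B. The E2F and G1/S list fell, with 26 of 53 members lower and 0 higher (29 adjusted over the list alone) and a median of -0.12 (camera adjusted p = 2.79e-11; adjusted p = 0.206 with an estimated correlation). The fall of that mean came mostly from Hep3B. MCM2, a subunit of the replicative helicase, fell by 0.27, and UHRF1, UNG and MCM4 each fell by 0.23. In the list of genes linked to ATAD2, 4 of 14 fell (7 adjusted over the list alone; camera adjusted p = 0.000363; adjusted p = 0.115 with an estimated correlation). Of the hepatocyte genes 14 fell and 5 rose (16 and 6 adjusted over the list alone; camera adjusted p = 0.0212; adjusted p = 0.395 with an estimated correlation), and that call was lost without Hep3B ATAD2 siRNA replicate 3 (0.0831), without PLC ATAD2 siRNA replicates 1 and 3 (0.0900) and with the 5' and 3' covariate (0.0630). S100A4, in the mesenchymal list, fell by 0.78, KLF4 rose by 0.56, and the lists of fatty acid, hypoxia and oxidative phosphorylation genes had medians of 0.03, -0.05 and -0.03 (camera adjusted p = 0.0212 each; adjusted p = 0.115, 0.478 and 0.478 with an estimated correlation). Of these, 10 of 29 fatty acid genes rose, and 7 of 33 hypoxia and 7 of 32 oxidative phosphorylation genes fell (10, 8 and 7 adjusted over the list alone). The fatty acid call was lost without the dimmest 30% (0.0635) or 50% (0.128) of genes and with the mean of all probe sets (0.161). The hypoxia call was lost without Hep3B ATAD2 siRNA replicate 1 (0.0656) or 3 (0.0831), with the 5' and 3' covariate (0.0801) and with median centring (0.0583). The oxidative phosphorylation call was lost with median centring (0.0833) and without Hep3B ATAD2 siRNA replicate 2 (0.0689) or PLC ATAD2 siRNA replicate 2 (0.0571).

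The response to knockdown differed between lines for 1815 genes (limma F test over the interaction contrasts). Some genes moved in opposite directions. CFDP1 changed by -0.05 in Hep3B, 0.73 in SNU449 and -0.17 in PLC, the metalloprotease gene ADAMTS1 by -0.49, 0.05 and 0.55, the phosphodiesterase gene PDE7B by -0.60, -0.01 and 0.40, the chemokine gene CXCL1 by 0.63, -0.17 and -0.34, and GPRC5B by -0.46, 0.43 and -0.31 (interaction adjusted p = 4.38e-07 to 0.000312). In all 34 genes passed the threshold in opposite directions in a pair of lines, 32 of them in Hep3B and PLC. Opposite calls were the exception in that pair, which shared 128 higher and 112 lower genes. Other large differences came from Hep3B, where LINC00621 changed by -2.04 against -0.27 in SNU449 and -0.48 in PLC, SLC39A10 by -2.04 against -0.25 and -0.28, TMF1 by -2.01 against -0.16 and 0.01, TECPR2 by 1.71 against 0.01 and 0.38, and ADAMTS3 by 2.05 against 0.03 and 0.07. Of the 2 other CFDP1 probe sets, 0 were called in SNU449. LINC00621, SLC39A10 and ADAMTS3 had a single probe set, and the other TECPR2 probe set was not called in Hep3B. Of the 5 other TMF1 probe sets, 1 was called in the opposite direction there and 0 in the same.

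By pair, 1918 genes differed in their response between PLC and Hep3B, 1214 between SNU449 and Hep3B and 40 between SNU449 and PLC. The hepatocyte list changed less in SNU449 than in PLC (SNU449 minus PLC 0.26, camera adjusted p = 1.02e-10; adjusted p = 0.0111 with an estimated correlation), although ALB, at 13.7 to 13.8 on the SNU449 arrays, lay at the top of the scale. The median difference of the list between PLC and Hep3B was -0.27 (adjusted p = 8.30e-08; adjusted p = 0.0442 with an estimated correlation). The list's signal on the Hep3B arrays was low, with a median of 5.06 to 5.12, and ALB, at 3.03 on the controls, had little room to fall. Some members were well expressed on the Hep3B controls, such as FGB (11.5), FGG (10.5) and C3 (8.66). The difference between PLC and Hep3B thus compares the response of expressed genes only in part. The E2F and G1/S list fell further in Hep3B than in SNU449 (median difference 0.24, camera adjusted p = 5.95e-17; adjusted p = 0.0686 with an estimated correlation) and than in PLC (0.22, adjusted p = 1.12e-08; adjusted p = 0.170 with an estimated correlation). The last difference was 0.09 on the deposited values and 0.03 with median centring. Of 47 list calls over all contrasts of the knockdown, the hepatocyte calls in PLC and in its differences from the other lines were the 3 that held with an estimated correlation. Without PLC ATAD2 siRNA replicate 2 the number of genes that differed between lines was 3644.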

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

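For the hepatocyte genes in PLC, the added covariate was chosen after the data were seen. For the genes lower in all 3 lines, the count of genes without another probe set, the other probe sets in SNU449 and PLC, and the share lower in Hep3B were chosen after the result was seen. All tests of the line labels were chosen after the result was seen. The other tests were written down before they were run.

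Hepatocyte genes fell in PLC (list median -0.23), and the list did not pass in SNU449 or Hep3B. In Hep3B the low median signal (5.06 to 5.12) left many members little room for a fall. Others were well expressed there, such as FGB (11.5) and FGG (10.5), and members past the threshold went both ways. Loss of 5' signal on ATAD2 siRNA replicates 1 and 3 predicts that the fall ends with 5' minus 3' signal as a covariate. The list still passed camera while its median shrank from -0.23 to -0.14, so that part of the fall goes with that signal. The covariate is 1 slope per gene, which rests largely on replicate 2 against the other ATAD2 siRNA arrays of PLC. It cannot show that the rest is free of array quality. A change that follows the expression level predicts equal falls in other genes of that level, but 0% of 10000 random lists matched on the PLC control level had a median as low (range -0.11 to 0.10). What remains is consistent with a loss of hepatocyte expression in this line. An effect of the siRNA on a transcript other than ATAD2 stays open, since 1 treatment per line was measured.

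Beside ATAD2, 6 genes were lower in all 3 lines. The signal of a single probe set predicts that other probe sets of these genes do not fall, and in Hep3B 100% of them, 4 of 4 from EDN1, HIKESHI and IGFBP3, were lower past the threshold. That explanation stays open in SNU449, where 0% passed although 4 of 4 lay below 0, and in PLC, where 50% passed and 1 EDN1 probe set lay above 0 (0.18), and for MRPS33, TXNDC16 and ZIC2, 3 genes with no other probe set. Direct silencing by the siRNA could not be told from an effect of ATAD2, because the siRNA sequence is not used here; among genes called in Hep3B with an absolute log2 change of at least 1, 58.8% were lower. Large falls of single genes such as MRPS33 would be in line with either.

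On the arrays labelled Hep3B hepatocyte genes were low and mesenchymal genes high, against what is known of that line. Exchange of the labels Hep3B and SNU449 predicts low RB1 under the SNU449 label, and the log2 difference was -5.03. Scaling between the lines predicts that the difference ends under another scaling, but the lowest median difference of the hepatocyte list was 3.35. A few arrays out of place predict overlap between the labels, but the lowest SNU449 array lay 3.69 above the highest Hep3B array. The values are consistent with an exchange of the names, which stays a hypothesis, since no genotype was measured here.

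Groups drawn by chance were set against the counts. With 10 splits of the 6 arrays of a line, too few for a share under 0.05, the real count was 3247 in Hep3B (highest other 1), 51 in SNU449 (0) and 904 in PLC (190). The same limit holds for the control arrays of each pair of lines, with 3899, 3642 and 3793 genes against 0 in any other split. Each other split mixes arrays of both lines within a group, so its count was low by design and decides nothing. Over 100 splits within the lines, 1 reached the real count for the mean change (2578, highest other 1717) and 1 for the genes shared by all lines (14, highest other 0), the real split in each case. In SNU449 no other split of the line called a gene, so splits that broke up its groups were near bound to share 0. That shared count was thus low largely by design and decides nothing. For the difference between lines 3 of 100 reached 1815, the real split and 2 others, with 2498 the highest other. Both others were among the 11 drawn splits that kept the Hep3B groups. The splits break up the knockdown effect within the lines, so they cannot decide whether the lines respond alike.

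A tested difference between lines brought up 1815 genes. In camera tests of each pair of lines, the lists differed between SNU449 and Hep3B by a median of 0.16 for genes linked to ATAD2, 0.24 for E2F and G1/S, 0.15 for G2/M, 0.10 for CDK inhibitors, -0.16 for stress response, 0.33 for TGF-beta, -0.19 for sterol, -0.11 for fatty acid, 0.12 for hypoxia, 0.10 for oxidative phosphorylation, -0.17 for NF-kB, 0.12 for immediate early and -0.13 for autophagy genes. Between PLC and Hep3B they differed by 0.17 for genes linked to ATAD2, 0.22 for E2F and G1/S, 0.20 for G2/M, -0.27 for hepatocyte, -0.28 for sterol, -0.11 for fatty acid, 0.12 for hypoxia, -0.28 for NRF2, -0.20 for NF-kB and -0.23 for autophagy genes. Between SNU449 and PLC they differed by 0.26 for hepatocyte and 0.21 for NRF2 genes. Only the hepatocyte differences held with an estimated correlation, and the one with Hep3B is limited by the low signal of many, though not all, of these genes there. Between SNU449 and Hep3B the call was lost in 10 of 30 settings for CDK inhibitors (camera adjusted p up to 0.313), 9 for fatty acid (0.136) and 6 for NF-kB genes (0.315), and between PLC and Hep3B in 6 each for genes linked to ATAD2 (0.287) and hypoxia genes (0.424).

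For single genes the highest minus the lowest log2 change of a line was 0.90 for CFDP1, 1.04 for ADAMTS1, 1.002 for PDE7B, 0.96 for CXCL1, 0.89 for GPRC5B, 1.77 for LINC00621, 1.79 for SLC39A10, 2.02 for TMF1, 1.70 for TECPR2 and 2.02 for ADAMTS3. Among genes shared by all lines it was 0.87 for DESI2, 0.59 for C19orf12, 0.77 for SMIM15, 0.42 for DENND5B, 0.44 for REV3L, 1.41 for ATAD2, 1.75 for TXNDC16, 1.47 for MRPS33, 1.33 for HIKESHI, 0.31 for IGFBP3 and 0.50 for EDN1. All these ranges are those of the main probe set of a gene. In Hep3B no other probe set of TMF1 or TECPR2 was called in the same direction, nor was any of CFDP1 in SNU449. Probe sets with no gene listed, which the gene tests leave out, held signal as well. Of 11721 such probe sets, limma called 385 in Hep3B (206 higher, 179 lower), 418 in PLC (236 higher, 182 lower) and 0 in SNU449.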

How the results depend on the processing

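Of the named genes and lists that were called, 1 gene turned direction (EBP in PLC) and the medians of 3 lists crossed 0 as their call was lost, NRF2 in PLC with the 5' minus 3' covariate (0.000446), autophagy in PLC without PLC ATAD2 siRNA replicates 1 and 3 (0.01) and genes linked to ATAD2 between PLC and Hep3B with median centring (-0.03). Where a value moved the cause was not tested unless fewer genes or arrays entered. At an adjusted p under 0.01 the counts higher and lower were 1106 and 874 in Hep3B, 4 and 5 in SNU449, 69 and 76 in PLC, 686 and 545 for the mean, 1 and 2 in all 3 lines, and 689 between lines. An absolute log2 change of at least 1 left 40 and 57, 0 and 1, 0 and 3, 0 and 3, 0 and 1, and 106, while without that minimum the control arrays gave 13128 (SNU449 and Hep3B), 13954 (PLC and Hep3B) and 14251 (SNU449 and PLC). Deposited values gave 4 shared lower genes and 8511 and 9424 genes between PLC and the other lines. Quantile normalization within lines gave 15 and 13 in SNU449, 3 shared higher genes, and 8349 and 9323. Median centring gave 827 lower in Hep3B, 74 and 13 in SNU449, 215 and 736 in PLC, 650 lower for the mean, 4 shared lower, and 8237 and 8577. Without the dimmest 30% SNU449 had 72 and 73 and all lines 15 and 11, and without the dimmest 50% SNU449 had 105 and 97, PLC 712 higher, all lines 23 and 14, and PLC and Hep3B controls 2416. The mean of probe sets gave 15 and 14 in SNU449 and 1 shared higher gene, and turned the change of EBP in PLC from -0.37 to 0.0527. Every probe set by itself gave 2776 higher in Hep3B, 11 and 13 in SNU449, 873 and 1008 in PLC, 1 shared higher, and 9362, 8663 and 9468 between controls. Each line by itself gave 6 and 10 in SNU449 and 3 and 12 in PLC. An intensity trend with a robust prior gave 72 and 52, 754 and 712, and 16 and 13 in all lines. A replicate block gave 3 and 5, 207 and 233, 0 and 2, and 1036 between lines. Control and ATAD2 siRNA arrays of the same number correlated weakly (9 pairs, r -0.125 to 0.0928). In PLC each control array correlated best with the ATAD2 siRNA array of its own number, as did 4 of 9 over all lines. Of the settings chosen after seeing the data, the 5' minus 3' covariate gave 161 and 233 in PLC, array weights gave 237 and 267 in SNU449, 745 and 729 in PLC, 27 and 19 in all lines and 3119 between lines, and leaving out PLC ATAD2 siRNA replicates 1 and 3 gave 46 and 39 in SNU449. In PLC the weights were 0.54 and 0.79 on ATAD2 siRNA replicates 1 and 3, which had low 5' signal, and 0.24 on replicate 2. The weighted fit thus does not correct for the loss of 5' signal. Leaving out each array in turn gave 1305 to 1984 higher and 1050 to 1747 lower in Hep3B, 5 to 50 and 5 to 36 in SNU449, 195 to 1698 and 207 to 1517 in PLC, 1094 to 1846 and 932 to 1749 for the mean, 1 to 14 and 2 to 11 in all lines, 1216 to 3644 between lines, and 3892 to 3939, 3624 to 3678 and 3793 to 3855 for the control arrays. The hepatocyte list in PLC passed in all 30 settings, with adjusted p of 5.66e-16 to 0.00773 and medians of -0.31 to -0.14. Settings that left out an array of another line kept the PLC changes and altered only the shared spread, so they tested little. Dim probe sets limit what the array can show, and of the 20 genes with the largest changes 19 in Hep3B, 7 in SNU449 and 16 in PLC kept their call without each array, and 18, 3 and 6 in every setting that tested them.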

Other observations

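In arrays labelled Hep3B, genes of several lists changed while the list did not pass camera. The fibrinogen genes FGG and FGA rose by 1.09 and 1.07 and the complement gene C3 by 0.77, within a hepatocyte list of 7 higher and 6 lower of 49 (10 and 6 adjusted over the list alone; camera adjusted p = 0.514). The keratin gene KRT7 fell by 1.08 and the tight junction gene CLDN1 rose by 0.92, with 3 of 28 epithelial genes higher and 4 lower. S100A4 fell by 1.65 and thrombospondin 1 (THBS1) by 0.99, while SPARC rose by 0.83 and the calponin gene CNN1 by 0.69. Among TGF-beta genes, JUNB fell by 1.05, SMAD6 by 0.81 and SMAD7 by 0.53, while the receptor gene TGFBR2 rose by 0.85 (2 of 21 higher and 7 lower; camera adjusted p = 0.0801).

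Apoptosis regulators moved both ways in Hep3B, with PMAIP1 down by 1.11, XIAP down by 0.90 and TNFRSF1A up by 0.59 (9 of 33 higher and 4 lower; camera adjusted p = 0.613). Interferon-stimulated genes showed no common shift, with IFIT1 down by 0.65 and ISG20 up by 0.48 (3 of 40 higher and 2 lower; camera adjusted p = 0.855). KLF4 rose by 1.12 in Hep3B and by 0.51 in SNU449, and changed by 0.05 in PLC (adjusted p = 0.779). No replication-dependent histone gene of 17 passed the threshold with limma in Hep3B.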
